A study of Netzelia tuberspinifera with 9 samples.

How the data were processed

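Total RNA of *Netzelia tuberspinifera*, a testate (shell-bearing) amoeba of the order Arcellinida, was sequenced in 9 libraries. Per the labels' protocols, cells were rinsed in sterile water, grown in medium in 24-well plates and held at 15, 25 or 35 °C for 24 h. RNA was taken up in Trizol and libraries were made with Illumina's standard protocols. The labels put 3 libraries in each temperature group and number them 1 to 3. They do not say whether the 3 libraries of a temperature came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

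The authors deposited 1 table per library, whose values are FPKM (mapped fragments scaled to the length of the contig and to the total of the library) per the file headers, written to 2 decimals. Each table lists the same 52063 assembled contigs, of which 34357 are called Unigene and 17706 are contigs of 6922 clusters, by their identifiers. Trimmomatic 0.36 and RSEM 1.2.8 are named in the submitters' processing notes, which give no role or setting for either. RSEM divides reads that match several contigs among them, so contigs of 1 cluster can share reads and their single values are uncertain. The assembler, the aligner and the assembly's version are not given in the sources used here. No annotation pairs the contigs with genes in the files used, so the identifiers are printed as given and no gene list fixed beforehand (chaperones, proteasome, antioxidant enzymes, ribosomal proteins, encystment, algal, bacterial or metazoan markers and others) could be tested. Abundance classes took their place, as fixed in that case: 3 classes of equal size of the tested transcripts, by mean log2(FPKM + 1) over the 9 libraries, and the 100 transcripts with the highest mean share of the FPKM sum.

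No read counts were used, so the absolute depth is unknown and no interval or detection floor that needs it is given. The relative depth of the libraries was estimated from contigs with 0.3 to 3 FPKM in both libraries of a pair, where most contigs hold few reads and the commonest ratio of values is the ratio of what 1 read is worth. Between 1799 and 7024 contigs entered per pair, the 36 pair ratios were joined by a fit of least absolute residuals (median residual 0.0036 on the log2 scale), and 1 pair, 15 °C replicates 1 and 3, lay more than 0.1 off the fit, with a residual of 1.02 in size. The relative depth of these libraries thus rests on their ratios to the other 7. Relative depth ran from 0.770 to 1.10 of the mean, a range of 1.43 times. A transcript with 0 FPKM is called listed at 0, since a 0 can also come from the estimation.

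The statistical design fixed before the data were examined assumed counts and named, for files without counts, the test used here. Differences were tested with limma 3.58.1 in R 4.3.3 (moderated test with a variance trend, robust off) on log2(FPKM + 1), over the 29138 transcripts with at least 1 FPKM in 3 or more libraries, 56.0% of the contigs. All 9 libraries entered 1 fit with 3 groups and 6 residual degrees of freedom, without a replicate block. Transcripts with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of transcripts of low level. The comparisons were 35 against 25 °C, 15 against 25 °C, 35 against 15 °C, any temperature, and the mean of 35 and 15 °C against 25 °C, which measures the departure from a straight line since the temperatures are evenly spaced. Overlaps between comparisons that share the 25 °C libraries were set beside 20 simulations of unchanged groups. Measures of whole libraries were compared with two-sided exact permutation tests, whose smallest possible p with 3 against 3 is 0.1, and 6 such tests form a family.

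The transcripts named in the text follow a rule set in advance. Among called transcripts whose libraries do not overlap between the groups and whose higher group averages at least 10 FPKM, they are the 2 with the largest rise and the 2 with the largest fall in each comparison. For the departure from a straight line, all 25 °C libraries had to lie above or below all 6 others. Sets defined by a mean under 0.5 FPKM at 15 °C were chosen after the data were seen.

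The test was run on simulated data with known changes in 200 transcripts before it was applied. The 29138 simulated transcripts had the real mean levels over the 9 libraries and the spread of the fit with 3 groups. Changed transcripts were drawn only from those with a mean log2(FPKM + 1) of at least 1, so the lowest transcripts are not covered. For 35 against 25 °C, rises of 2, 4, 8 and 16-fold on the FPKM + 1 scale were called in 8%, 52%, 100% and 100% of 25 each. Falls of the same sizes were called in 0%, 36%, 44% and 48%, because values were kept at 0 or above. Unchanged transcripts made up 6.73% of the calls in that simulation, 11.4% in the one for 15 against 25 °C and 7.27% in the one for 35 against 15 °C, all above the nominal 5%. These shares are imprecise, since each comes from 1 simulation with 104, 105 and 110 calls. The simulation gave the 3 groups of a transcript the same spread, so the shares do not measure the error rate of the real calls. Alternatives tried were the pseudocount, the filter on low values, quantile normalization, 4 scalings of the FPKM columns computed from the values (trimmed mean of log ratios, median ratio, upper quartile and equal totals), sums over the contigs of a cluster, fits on only the groups compared, a replicate block, a minimum log2 difference of 1, and leaving out each library in turn or a pair of libraries that stood apart from the rest.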

Results

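The series asked how *Netzelia tuberspinifera*, a testate amoeba endemic to East Asia and described by the submitters as sensitive, responds to warming at the transcript level. A set of 9 libraries of total RNA, 3 per temperature, covered 24 h at 15, 25 and 35 °C. Transcript levels were given in FPKM for 52063 assembled contigs, and the 25 °C libraries served as the middle of the gradient. The identifiers carry no gene names, so transcripts are described by level, direction and group size.

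More transcripts were detected at 35 °C than at either lower temperature. At 1 FPKM or more, 27711 ± 580 transcripts were detected at 35 °C, 21616 ± 1402 at 25 °C and 23374 ± 1925 at 15 °C (SD, n = 3). All 3 libraries at 35 °C lay above all 6 others. The difference of 6095 transcripts between 35 and 25 °C and that of 4337 between 35 and 15 °C each had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow (adjusted 0.20 over 6 tests), and 15 against 25 °C gave an exact p of 0.3 (adjusted 0.45). The size of these differences depends on the minimum level. At 10 FPKM or more they were 1000 for 35 against 25 °C and 618 for 35 against 15 °C, and at 0.1 FPKM or more 8322 and 4556. The 100 most abundant transcripts held 35.6 ± 3.78% of the FPKM sum at 35 °C, 40.4 ± 1.74% at 25 °C and 37.8 ± 5.25% at 15 °C (SD, n = 3), with exact permutation p of 0.1 for 35 against 25 °C, 0.7 for 15 against 25 °C and 0.5 for 35 against 15 °C (adjusted 0.20, 0.70 and 0.60). Relative depth averaged 0.918 ± 0.134 at 35 °C, 1.08 ± 0.0245 at 25 °C and 1.003 ± 0.162 at 15 °C (SD, n = 3). Replicate 2 at 35 °C and replicate 3 at 15 °C, with relative depths of 0.770 and 0.816, stood apart from the other libraries in their most abundant transcripts, whose top 100 took 31.3% and 31.8% of their FPKM sums.

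**Figure D1:**
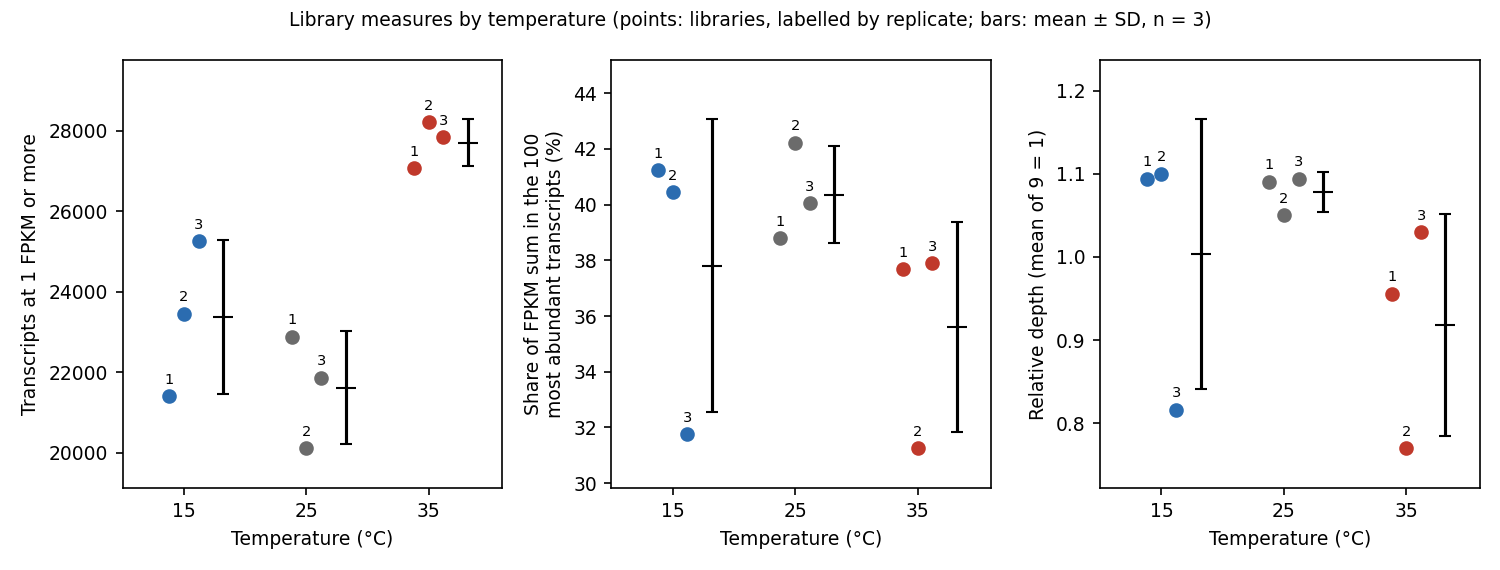
Transcripts at 1 FPKM or more, percent of the FPKM sum in the 100 most abundant transcripts, and relative depth (9-library mean set to 1), plotted against temperature in °C, with 1 point per library, its replicate number, and the mean ± SD (n = 3) as a bar; the axes do not start at 0. The 3 libraries at 35 °C, from 27078 to 28218 transcripts, lie above all others, and 35 °C replicate 2 and 15 °C replicate 3 lie lowest in the middle and right panels.

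Between the temperature groups, 2350 of 29138 tested transcripts (8.07%) differed when all 3 groups were compared at once (limma, adjusted p under 0.05). At that threshold, 2349 transcripts differed between 35 and 25 °C, 1677 between 35 and 15 °C, and 185 between 15 and 25 °C. The labels do not show separate cultures and the organism of a contig was not checked, so these counts do not single out a response of the amoeba to temperature. The order of the last 2 comparisons depends on the threshold. At an unadjusted p under 0.05 the counts were 5878, 3130 and 4246, and the 3 libraries of a temperature lay wholly apart from those of the other in 25.0%, 15.6% and 17.5% of the transcripts, where chance gives 10%. Transcripts higher at 35 °C than at both other temperatures numbered 1457, against 1 that was lower at 35 °C than at both. At 25 °C, 107 transcripts were lower and 7 higher than at both others, and at 15 °C 23 were lower and 15 higher than at both others. Without 35 °C replicate 2 and 15 °C replicate 3, 1231 transcripts changed with temperature and 872 were higher at 35 °C than at both others, while the sets lower at 25 °C, higher at 25 °C, lower at 15 °C and higher at 15 °C than at both others held 2, 0, 4 and 3. Leaving out any one of the 35 °C libraries left 0, 0, 3 and 0 in these sets. Quantile normalization gave 957 transcripts higher and 5 lower at 35 °C than at both others, and 68 lower and 22 higher at 25 °C than at both others; upper quartile scaling gave 1325 and 10, and 81 and 22. With a filter at 5 FPKM, 528 were higher at 35 °C than at both others.

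The comparison of 35 with 25 °C was marked by transcripts that were higher at 35 °C from low or no signal at 25 °C. Of the 2349 changed transcripts, 2248 were higher at 35 °C (95.7%) and 101 were lower. Among the risers, 984 (43.8%) were listed at 0 in all 3 libraries at 25 °C and have no fold change; the other 1264 rose by a median log2 difference of 2.45. The median riser averaged 6.70 FPKM at 35 °C, 829 averaged 10 FPKM or more there and 61 averaged 100 FPKM or more. Together the risers made up 3.001, 3.67 and 3.88% of the FPKM sum in the 35 °C libraries and 0.698, 0.480 and 0.484% in the 25 °C libraries. The transcripts lower at 35 °C held 0.958 to 1.37% of the sum at 25 °C and 0.454 to 0.545% at 35 °C.

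The largest rise at 35 °C belonged to CL5322.Contig1_All, with 52.4, 101 and 87.5 FPKM in the 3 libraries at 35 °C against 2.58, 0 and 0 at 25 °C (log2 difference 5.68, SE 0.57, limma adjusted p = 0.000572). Unigene13185_All followed with 66.9, 55.2 and 85.1 FPKM at 35 °C against 2.38, 0.10 and 0 at 25 °C (log2 difference 5.48, SE 0.54, limma adjusted p = 0.000572). The largest fall was that of CL449.Contig1_All, from 79.4, 247 and 124 FPKM at 25 °C to 2.21, 0 and 15.3 at 35 °C (log2 difference -5.18, SE 1.36, limma adjusted p = 0.0318). Unigene26390_All went from 20.1, 30.0 and 54.8 FPKM to 0, 0 and 7.87 (log2 difference -4.00, SE 1.15, limma adjusted p = 0.0493). Both falls passed the threshold narrowly and lost it with a pseudocount of 0.1. Of 21 alternatives, CL449.Contig1_All lost its call in 7 (limma adjusted p up to 0.194) and Unigene26390_All in 11 (limma adjusted p up to 0.234). Both transcripts were also listed at 0 in 15 °C replicate 3, 1 of the libraries that stood apart. In each of the 4, all 3 libraries at 35 °C lay on the same side of all 3 at 25 °C, which the rule for naming transcripts required.

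The classes by abundance use the mean over all 9 libraries, so a rise from 0 to a few FPKM itself places a transcript in a low class, and the counts do not show that low transcripts responded more often. In the least abundant class of 9712 transcripts (median 1.13 FPKM), 1150 were higher and 27 lower at 35 °C than at 25 °C. In the middle class of 9713 (median 3.01 FPKM), 676 were higher and 19 lower, and in the most abundant class of 9713 (median 18.5 FPKM), 422 were higher and 55 lower. Adjusted over each class alone, the counts were 1277 and 42, 620 and 15, and 322 and 24. Of the 100 most abundant transcripts, none was called higher and 1 lower (none at all when adjusted over these 100 alone). The median log2 difference of all tested transcripts was 0.29 in favour of 35 °C. It was 0.04 after upper quartile scaling and -0.09 after quantile normalization, and the split of calls was then 1725 higher and 263 lower, or 1249 higher and 233 lower (84.3% higher). Leaving out 25 °C replicate 3 reduced the 2349 calls to 1353. Simulated falls of 8-fold (on the FPKM + 1 scale) were called in 44% of cases and simulated rises in 100%, so falls were less detectable than rises at the simulated levels. Those levels leave out the lowest transcripts, and 1561 of the 2248 risers averaged under 1 FPKM at 25 °C. Counted without a test, the 3 libraries at 35 °C lay above all 3 at 25 °C in 5675 transcripts and below them in 1617, together 25.0% of those tested where chance gives 10%.

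**Figure D2:**
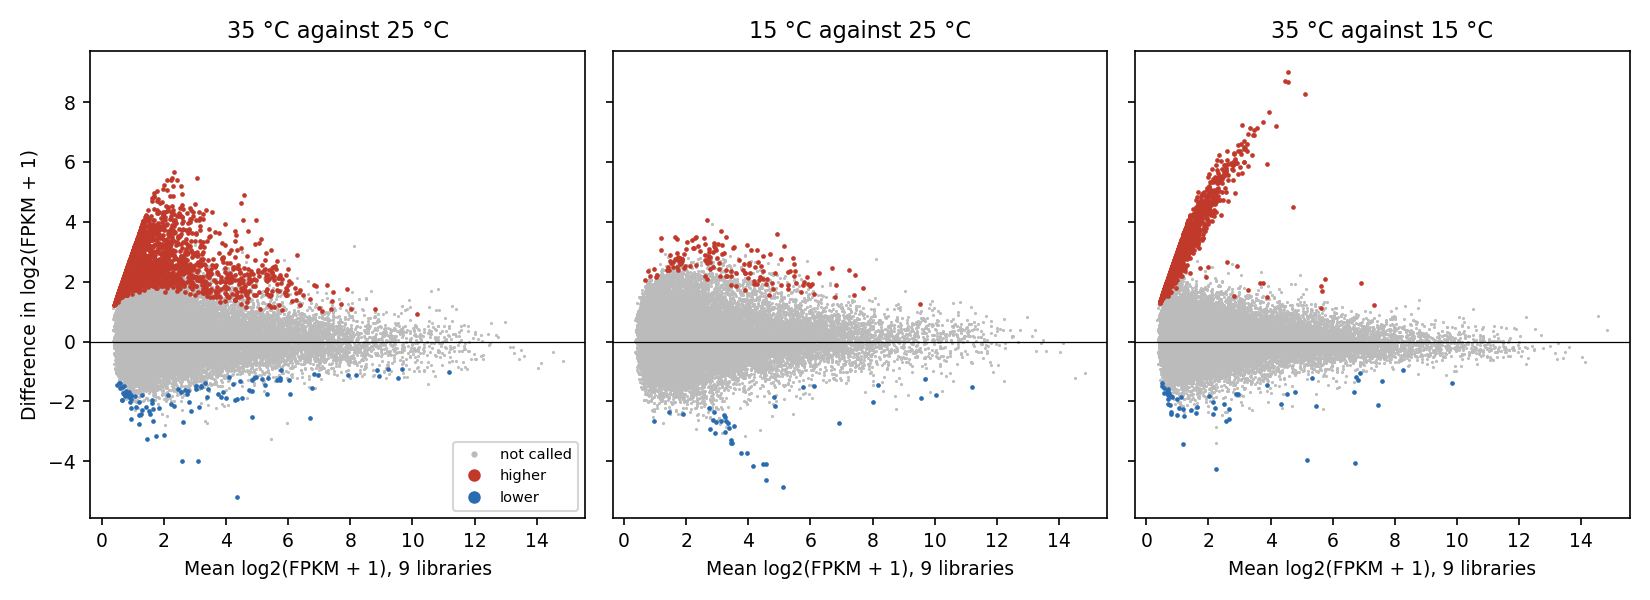
Difference in log2(FPKM + 1) against mean log2(FPKM + 1) over the 9 libraries, 1 point per tested transcript, for the 3 pairs of temperatures; red points are called higher in the first-named group, blue points lower (limma, adjusted p under 0.05), and grey points are not called. The 2248 rises at 35 °C against 25 °C and the 1623 against 15 °C lie mainly at low mean levels, and 185 transcripts are called between 15 and 25 °C.

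The comparison of 35 with 15 °C, the full span of the gradient, separated a block of transcripts that were nearly absent at 15 °C. Of 1677 transcripts that differed, 1623 were higher at 35 °C (96.8%) and 54 were lower. Among the 1623, 1271 (78.3%) were listed at 0 in all 3 libraries at 15 °C, and 1598 averaged under 0.5 FPKM there. These 1598 transcripts, called the 15 °C-absent block below, averaged a median of 5.74 FPKM at 35 °C, and 20 of them reached 100 FPKM. The block's share of the FPKM sum was 1.31, 2.05 and 1.95% in the 35 °C libraries, 0.117, 0.162 and 0.0443% in the 25 °C libraries, and 0.000487, 0.000875 and 0.00691% in the 15 °C libraries. It holds 1442 of the 2248 transcripts higher at 35 than at 25 °C. Without the pair of libraries that stood apart, 989 transcripts differed between 35 and 15 °C, 939 formed such a block and 867 of these were also higher at 35 than at 25 °C. Leaving out 15 °C replicate 2 reduced the 1677 calls to 1069.

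Unigene989_All rose from 0.147 ± 0.0115 FPKM at 15 °C through 19.1 ± 5.36 at 25 °C to 595 ± 109 at 35 °C (SD, n = 3), a log2 difference of 9.01 between 35 and 15 °C (SE 0.33, limma adjusted p = 1.27e-08). CL6001.Contig1_All had 0.157 ± 0.0404, 25.9 ± 18.8 and 517 ± 234 FPKM at 15, 25 and 35 °C (SD, n = 3), with a log2 difference of 8.72 between 35 and 15 °C (SE 0.63, limma adjusted p = 8.82e-06). The opposite course was rare. Unigene4682_All had 446 ± 255 FPKM at 15 °C, 133 ± 12.6 at 25 °C and 24.0 ± 12.4 at 35 °C (SD, n = 3; log2 difference -4.05 between 35 and 15 °C, SE 0.49, limma adjusted p = 0.000288). Unigene18887_All had 43.8, 25.7 and 13.7 FPKM at 15 °C and 0, 0 and 1.44 at 35 °C (log2 difference -4.27, SE 0.56, limma adjusted p = 0.000499). All 4 kept their direction and their call in each of the 21 alternatives tried for them.

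A graded rise at each step was seen in 22 transcripts, called lower at 15 than at 25 °C and higher at 35 than at 25 °C. Their median levels were 0.07, 9.78 and 127 FPKM at 15, 25 and 35 °C, and 15 of the 22 reached 100 FPKM at 35 °C. Their log2 differences between 35 and 15 °C ran from 5.39 to 9.01. The size of the set depends on the libraries in the fit. It held 4 transcripts without the pair of libraries that stood apart and 3 without any one of the 35 °C libraries. It held 10, 5 and 10 without 15 °C replicates 1, 2 and 3, and 15, 10 and 30 without 25 °C replicates 1, 2 and 3. Leaving out a 35 °C library cannot alter the difference between 15 and 25 °C. Calls of that difference were then lost through the estimated spread and the adjustment, not through smaller differences. No transcript was called in the reverse order, higher at 15 and lower at 35 °C than at 25 °C.

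The 806 transcripts higher at 35 than at 25 °C that fell outside the 15 °C-absent block were low at 25 °C and less so at 15 °C. Their median levels were 6.66, 1.08 and 9.64 FPKM at 15, 25 and 35 °C. In 780 of them the 15 °C mean lay above the 25 °C mean on the log2 scale, with a median difference of 1.68, but only 107 passed the test for it and 15 differed between 35 and 15 °C. The medians of the single libraries were 4.99, 6.22 and 7.32 FPKM at 15 °C and 1.53, 0.28 and 0.79 at 25 °C. Part of this can come from the shared 25 °C libraries, because transcripts picked for being low at 25 °C against 35 °C also tend to be low there against 15 °C. Another part is set by the choice of the 806 itself, which leaves out transcripts with a 15 °C mean under 0.5 FPKM that were called higher at 35 than at 15 °C. Without the pair of libraries that stood apart, 717 such transcripts were called and 439 of them had a positive difference between 15 and 25 °C.

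Presence and absence followed the same course. Transcripts with at least 1 FPKM in all 3 libraries at 35 °C and 0 in all 3 at another temperature numbered 1127 against 25 °C and 1371 against 15 °C. In the opposite direction 13 were present at 25 °C and 18 at 15 °C while listed at 0 in all libraries at 35 °C; without the pair of libraries that stood apart, which loosens the rule, these were 58 and 259, and the 18 became 104 without 15 °C replicate 3 alone. Between the lower temperatures, 191 were present at 15 and listed at 0 at 25 °C, and 41 the reverse. Present at 35 °C and listed at 0 in all 6 other libraries were 758 transcripts, against 2 for 25 °C and 6 for 15 °C. These 758 had modest levels, with quartiles of 2.70, 3.73 and 5.62 FPKM and a maximum of 19.0 FPKM, and their 10 most abundant members held 4.5% of the set's FPKM. They made up 0.233 to 0.345% of the FPKM sum at 35 °C. No test was applied to these counts; without the pair of libraries that stood apart they were 1112 at 35 °C, 14 at 25 °C and 97 at 15 °C.

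Between 15 and 25 °C, 185 transcripts were called, of which 147 were higher and 38 lower at 15 °C. The libraries lay wholly above those at 25 °C in 3428 transcripts and wholly below in 1668, together 17.5% where chance gives 10%, so the count of calls does not show that few transcripts differed. The 125 risers with some signal at 25 °C had a median log2 difference of 2.49, and 106 of the 147 averaged 10 FPKM or more at 15 °C. The largest rises were those of CL4560.Contig3_All, from 0.45, 0 and 1.99 FPKM at 25 °C to 42.9, 24.2 and 17.4 at 15 °C (log2 difference 4.07, SE 0.58, limma adjusted p = 0.0151), and CL3818.Contig2_All, from 0.33, 0 and 7.79 to 41.4, 31.4 and 17.7 FPKM (log2 difference 3.70, SE 0.72, limma adjusted p = 0.0442). The largest falls were those of Unigene16674_All, from 65.9, 72.3 and 22.2 FPKM at 25 °C to 0, 0.12 and 3.09 at 15 °C (log2 difference -4.87, SE 0.55, limma adjusted p = 0.00490), and Unigene14860_All, from 28.9 ± 15.4 to 0.0867 ± 0.0551 FPKM (SD, n = 3; log2 difference -4.62, SE 0.44, limma adjusted p = 0.000732). At 35 °C these last transcripts stood at 527 ± 134 and 461 ± 141 FPKM (SD, n = 3), and both are among the 22 that rose at each step.

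By abundance, 8, 38 and 101 transcripts were higher at 15 than at 25 °C in the least abundant, middle and most abundant classes, and 1, 2 and 35 were lower. Adjusted over each class alone the counts were 0 and 0, 8 and 0, and 257 and 93. Of the 100 most abundant transcripts 1 was lower and none higher (2 lower and 1 higher adjusted over these 100 alone). The 185 calls rest on small margins. A fit on the 6 libraries at 15 and 25 °C alone called 0 transcripts (3658 at an unadjusted p under 0.05; 4246 in the fit of all 9), and without the pair of libraries that stood apart 8 were called. Leaving out 1 library gave 3 calls without any one of the 35 °C libraries, 15 without 15 °C replicate 2, 41 and 67 without 25 °C replicates 2 and 3, 51 and 47 without 15 °C replicates 1 and 3, and 241 without 25 °C replicate 1. Quantile normalization gave 102 higher and 67 lower. All 4 named transcripts kept their direction in each of 21 alternatives, but CL3818.Contig2_All lost its call in 14 of them (limma adjusted p up to 0.213), CL4560.Contig3_All in 6, Unigene16674_All in 4 and Unigene14860_All in 1.

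**Figure D3:**
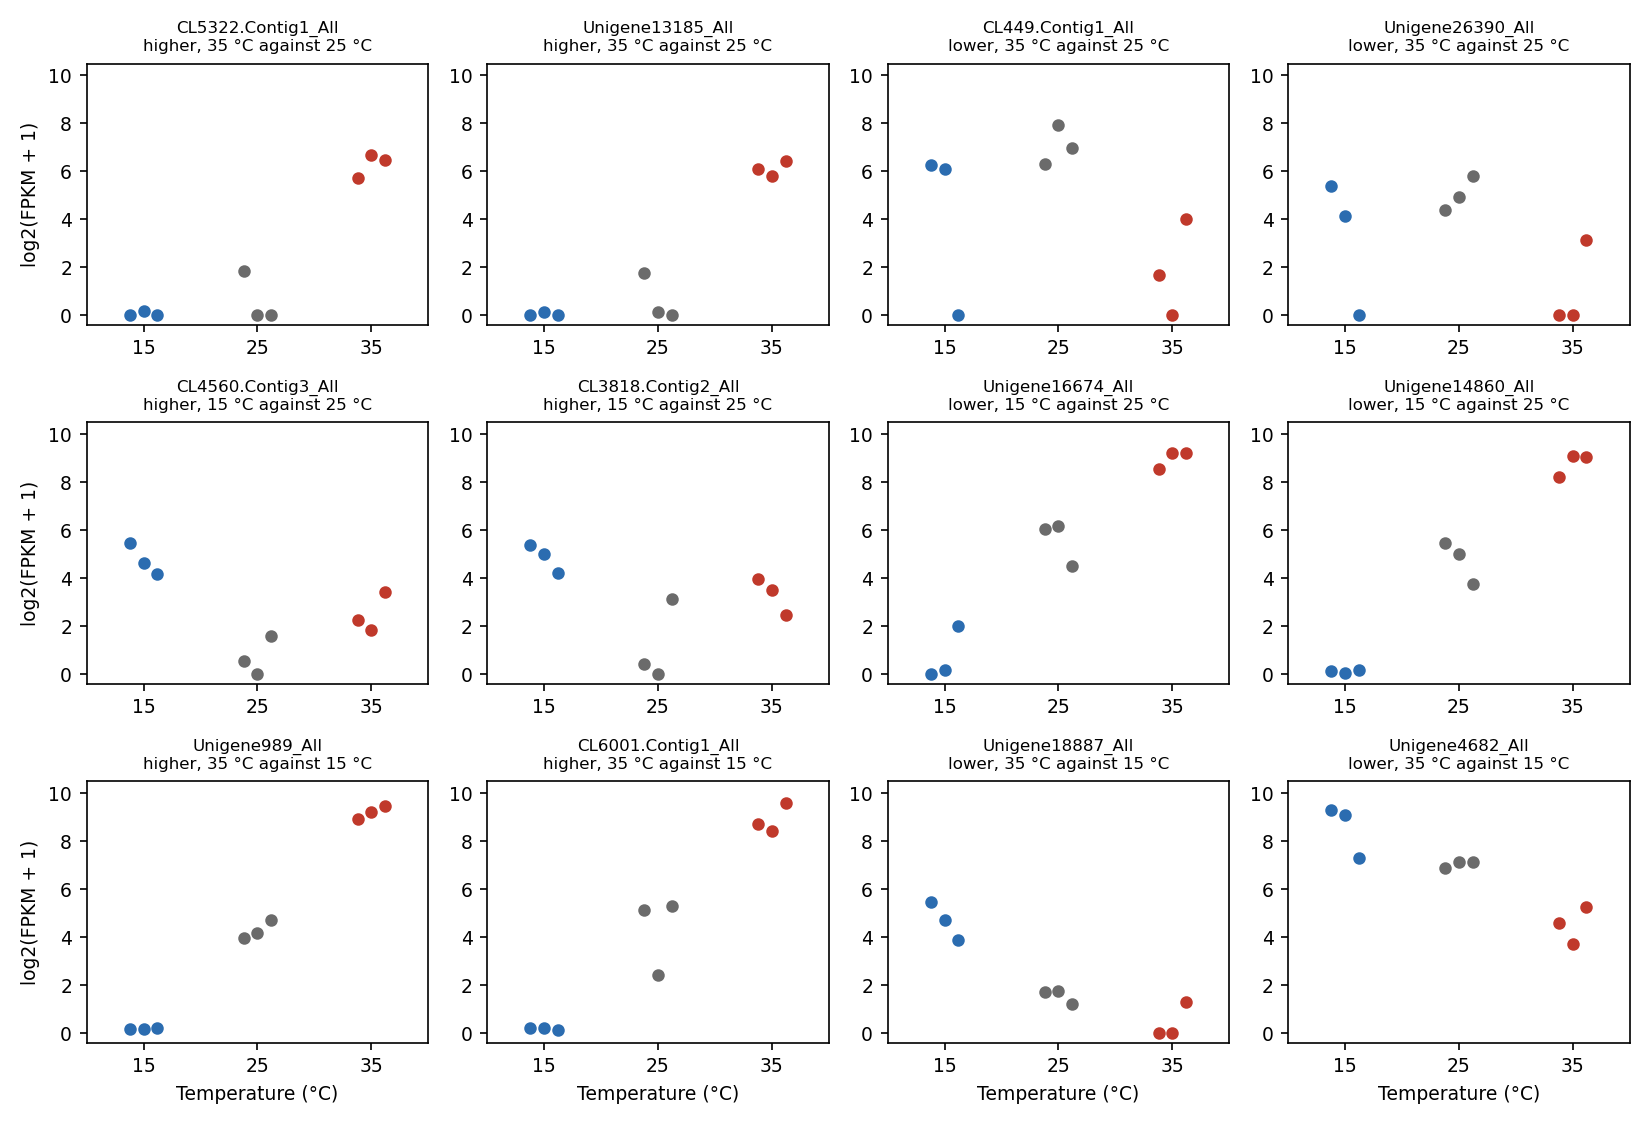
Log2(FPKM + 1) of the 12 named transcripts of the pairwise comparisons against temperature in °C, 1 point per library (3 per temperature), with the comparison that named each transcript in its title. Unigene989_All stands near 0 at 15 °C and above 488 FPKM in every 35 °C library, and Unigene4682_All falls from a mean of 446 FPKM at 15 °C to 24.0 FPKM at 35 °C.

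Transcripts changed in the same direction at 35 and at 15 °C, both against 25 °C, numbered 107 higher and 7 lower, and 22 went in opposite directions. Independent lists of these sizes would share 11.3 higher and 0.132 lower. Simulated unchanged groups gave almost no calls, so they give no measure of the overlap that shared controls alone would cause in lists of this size. Across transcripts, which are not independent replicates, the log2 differences of both comparisons correlated at 0.46, against a mean of 0.50 in 20 simulations of unchanged groups against the same 25 °C libraries. Their covariance was 0.362 against 0.146, a difference of 0.216, and 73.0% had the same sign against 66.6%. The correlation lay below all 20 simulations (0.488 to 0.510), and only the covariance and the same-sign share exceeded them. With 3 libraries at 25 °C the controls could not be split, so part of the excess in these measures and in the shared calls may come from the shared controls. Quantile normalization gave 68 higher and 22 lower in both comparisons, and upper quartile scaling 81 and 22. The shared calls in 1 direction, 114 in all, fell to 2 without the pair of libraries that stood apart. Leaving out 1 library gave 0 without any one of the 35 °C libraries, 34, 8 and 19 without 15 °C replicates 1, 2 and 3, and 187, 25 and 27 without 25 °C replicates 1, 2 and 3.

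The departure from a straight line, the mean of 35 and 15 °C against 25 °C, was called in 652 transcripts, 581 with lower and 71 with higher levels at 25 °C than the line between the outer temperatures gives. A transcript raised only at 35 °C can also lie below that line at 25 °C, so the 581 are not a count of dips. Called lower at 25 °C than at both others were 107. The transcripts named here dip or peak at 25 °C because the naming rule required it. Unigene18137_All had 6.11 ± 4.09 FPKM at 25 °C against 59.6 ± 11.4 at 35 °C and 74.6 ± 12.6 at 15 °C (SD, n = 3; log2 difference 3.43, SE 0.37, limma adjusted p = 0.00827). CL2639.Contig3_All was listed at 0 in all 3 libraries at 25 °C and had 13.8, 10.2 and 22.1 FPKM at 35 °C and 16.3, 2.93 and 10.1 at 15 °C (limma adjusted p = 0.00864). In the other direction, CL1718.Contig1_All stood at 77.5 ± 6.34 FPKM at 25 °C against 12.8 ± 2.07 at 35 °C and 20.7 ± 3.38 at 15 °C (SD, n = 3; log2 difference -2.19, SE 0.26, limma adjusted p = 0.00827). Unigene16605_All had 13.01 ± 2.35 FPKM at 25 °C against 2.14 ± 0.650 at 35 °C and 2.57 ± 2.51 at 15 °C (SD, n = 3; log2 difference -2.20, SE 0.49, limma adjusted p = 0.0392). The call of Unigene16605_All was lost in 10 of 20 alternatives (limma adjusted p up to 0.146), among them a pseudocount of 0.1 and leaving out any one of the 25 or 35 °C libraries. Quantile normalization gave 221 lower and 103 higher at 25 °C. Without the pair of libraries that stood apart no departure was called (5626 at an unadjusted limma p under 0.05). Leaving out 1 library gave 0 without 35 °C replicate 1 or replicate 3 and 73 without 35 °C replicate 2. It gave 546, 71 and 68 without 25 °C replicates 1, 2 and 3, and 498, 107 and 317 without 15 °C replicates 1, 2 and 3.

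In the most abundant transcripts the libraries did not all group by temperature. Over the 1451 transcripts with a mean above 100 FPKM, the spread of log2 ratios (median absolute deviation) between 35 °C replicate 2 and 15 °C replicate 3 was 0.30, and each of the pair differed from the other 7 libraries by 0.62 to 1.26. Replicates 1 and 3 at 35 °C differed by 0.19 and replicates 1 and 3 at 25 °C by 0.25. Replicate 2 at 25 °C also lay far from the rest, by 0.71 and 0.62 from its own group and up to 1.26 from the others, and replicate 1 at 15 °C differed from the others by 0.47 to 1.06. The labels give no batch or date, so no value within batches can be given.

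**Figure D4:**
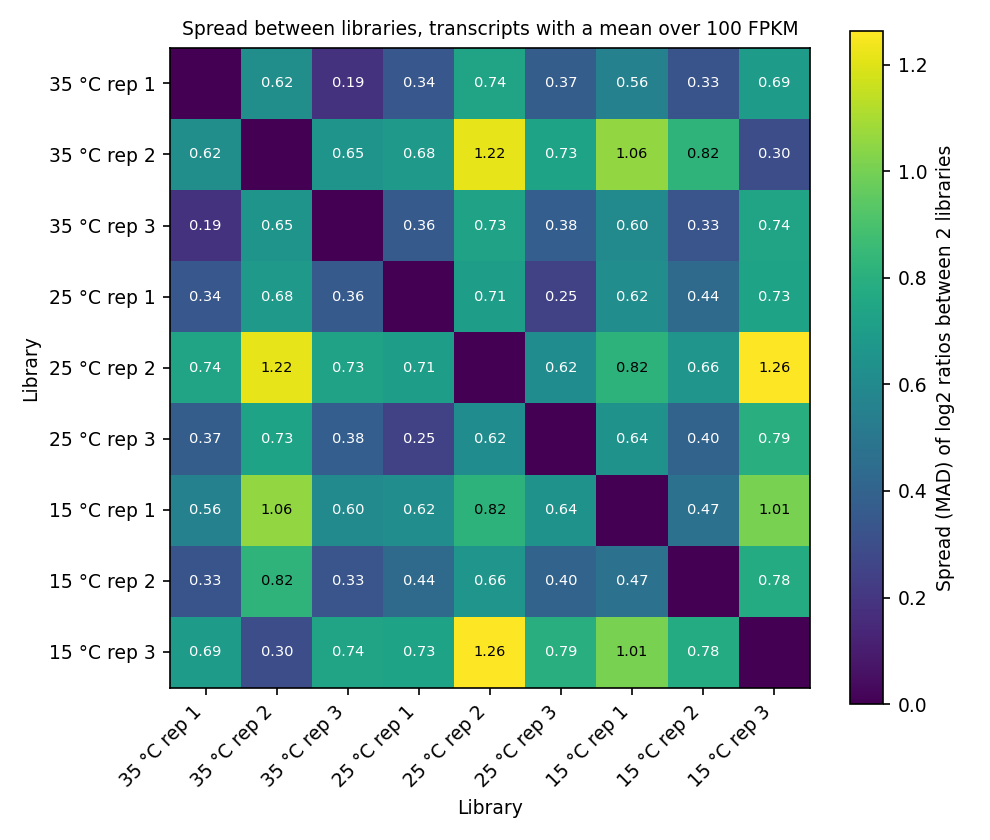
Spread (median absolute deviation) of log2 FPKM ratios between each pair of the 9 libraries, over the 1451 transcripts with a mean above 100 FPKM; both axes list the libraries, the colour scale is in log2 units, and the diagonal carries no value. The pair of 35 °C replicate 2 and 15 °C replicate 3 has 0.30, while each differs from the other 7 libraries by at least 0.62.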

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

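The scalings of the FPKM columns, the cluster sums, the fit without 35 °C replicate 2 and 15 °C replicate 3, the 5 FPKM filter and the FPKM minima for presence and detection were chosen after seeing the data; the others were set beforehand. Alternatives set beforehand that need read counts (count-based normalizations and tests, voom weights, thinning of counts, minima in counts or CPM) were not run, because the values are FPKM. The cause of a change was not tested, except where fewer libraries or transcripts entered by construction. Depth limits the low end: a 0 cannot be told from a level under what 1 read is worth.

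Calls at 35 against 25 °C (2349) fell to 1082 with a filter at 5 FPKM, which tests fewer transcripts, and to 1482 with quantile normalization; leaving out 1 library gave 1353 to 2297. At 35 against 15 °C (1677) they were 600 with the 5 FPKM filter, 989 without the pair and 1069 (without 15 °C replicate 2) to 1655 without 1 library. Any temperature (2350) gave 1117 with the 5 FPKM filter, 1231 without the pair and 1671 to 2115 without 1 library. At 15 against 25 °C (185) they were 108 with no filter, 387 with the 5 FPKM filter, 114 with median-ratio scaling, 91 with equal totals, 80 with cluster sums, 8 without the pair, 0 with only both groups compared and 3 to 241 without 1 library. Departures from a straight line (652) were 1380 with a pseudocount of 0.1, 384 with no filter, 324 with quantile normalization, 315 with upper quartile scaling, 365 with cluster sums, 0 without the pair and 0 to 546 without 1 library. Shared calls in 1 direction (114) were 72 with no filter, 210 with the 5 FPKM filter, 71 with median-ratio scaling, 54 with equal totals, 45 with cluster sums, 2 without the pair and 0 to 187 without 1 library. Transcripts higher at 35 °C than at both others (1457) were 528 with the 5 FPKM filter, 957 with quantile normalization, 872 without the pair and 976 to 1383 without 1 library. Apart from the replicate block, the other alternatives run left these counts within 1.5 times; cluster sums and the minimum log2 difference were not run for the 1457.

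A replicate block gave 1865 calls at 35 against 25 °C, 1507 at 35 against 15 °C, 1856 for any temperature, 31 at 15 against 25 °C, 144 departures from a straight line and 15 shared calls. Deviations of libraries with the same number correlated between -0.27 and 0.16, and 2 of 9 libraries correlated best with their own number, so the numbers are not taken to pair samples.

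The difference in detected transcripts between 35 and 25 °C (6095) was 8322 at 0.1 FPKM and 1000 at 10 FPKM, that between 15 and 25 °C (1758) was 3766 at 0.1 FPKM and 382 at 10 FPKM, and that between 35 and 15 °C (4337) was 618 at 10 FPKM; without 1 library they were 5341 to 6728, 818 to 2741 and 3354 to 5277. The difference in the share of the 100 most abundant moved by less than 1 SD, pooled over both groups compared, in every alternative, and without 1 library it was -5.89 to -2.56 points (35 against 25 °C), -4.25 to 0.49 (15 against 25 °C, positive only without 15 °C replicate 3) and -5.23 to -0.024 (35 against 15 °C).

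With minima of 0.5 and 2 FPKM, transcripts present at 35 and at 0 at 25 °C were 1686 and 530, at 35 not 15 °C 1734 and 877, at 25 not 35 °C 44 and 5, at 25 not 15 °C 76 and 15, at 15 not 35 °C 65 and 4, and at 15 not 25 °C 443 and 58. In the same order they were 1633, 2112, 58, 96, 259 and 414 without the pair. Without 1 library, which loosens the rule, they were 1431 to 1980, 1422 to 2060, 26 to 76, 52 to 186, 32 to 104 and 298 to 550.

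The 16 named transcripts had 332 alternative values in all: 270 kept direction and call, 62 kept direction and lost the call (39 of them without 1 library), and 0 changed direction. Of the 16, 6 kept their call in every alternative: CL5322.Contig1_All, Unigene13185_All, Unigene989_All, CL6001.Contig1_All, Unigene18887_All and Unigene4682_All. The 4 of the departure from a straight line and 2 of the 15 against 25 °C comparison (CL4560.Contig3_All, CL3818.Contig2_All) lost it without the pair, as did Unigene26390_All at 35 against 25 °C (adjusted p 0.0535; 0.00668 to 0.234 over its alternatives).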

Other observations

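The tests of depth, of the shared batch, of the scaling and of the fixed-profile source for transcripts nearly absent at 15 °C were chosen after the result was seen. The counts of trios and pairs of libraries and the comparison within the 15 °C-absent block were not set beforehand either. Tests of exchanged labels, of mixing, of the fixed-profile source for rises measured at both temperatures and of other divisions of the libraries were set before their results were seen.

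Exclusive presence set the 35 °C libraries apart from every other trio. Among the 84 possible trios of the 9 libraries, the 35 °C trio shared 758 transcripts with at least 1 FPKM in all 3 and 0 in the other 6, and the highest other trio had 42. Within the 15 °C-absent block, 217 transcripts averaged 20 FPKM or more at 35 °C. As a set, though not in each member, they were lower in 35 °C replicate 1 than in replicates 2 and 3. Their median log2 ratio to the 35 °C mean was -0.46 in replicate 1 against 0.16 and 0.20 in replicates 2 and 3, while the 4102 uncalled transcripts in the same range had 0.00, 0.03 and -0.06. Replicate 1 was lowest of the 3 for 66.4% of the 217 and for 24.2% of those 4102. Summed over the 217 and relative to their 35 °C level, they stood at 7.31, 10.3 and 2.74% in the 25 °C libraries. In the 15 °C libraries they stood at 0.0237, 0.0356 and 0.314%. Single members did not all follow these sums.

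The excess of rises at 35 °C was weighed against technical explanations. The estimated relative depth of the 35 °C libraries was 0.852 of that at 25 °C, which argues against greater depth as the cause. It does not exclude it, since the estimate was made without read counts. The 35 °C libraries also listed more transcripts above 0, on average 35386 against 27253 at 25 °C. That count does not settle the question, because the rises themselves add to it. Most calls (84.3%) were still rises after quantile normalization, so the excess did not vanish with another scaling. Rises then numbered 1249 instead of 2248, however, and falls 233 instead of 101. Falls were also harder to call than rises in the simulations, so this share does not exclude scaling as the source of part of the excess. A candidate source is RNA of another organism in the wells, added in 1 proportion per library with a fixed profile. For rises measured in all 6 libraries (317), their log2 differences spread 1.37 times their error, between the bounds set for and against; for the block, ratios of the 25 °C to the 35 °C level correlated at -0.11 between the 25 °C libraries (64 transcripts), but level-matched uncalled transcripts reached only 0.18, so the test has little power and both parts cannot be told apart from a response of the amoeba. The lower power for falls (44% against 100% of simulated 8-fold changes) can add to the excess by an amount that was not measured, a response of the amoeba to heat stays open and untested, and no sequence was used here that names the organism of a contig.

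The likeness of 35 °C replicate 2 and 15 °C replicate 3 was weighed as well. In the 1451 transcripts above 100 FPKM, the pair lay below all 7 others in 397 and above them in 288 (chance gives 2.78% for either direction), and no other pair reached more than 267 in sum. An exchange of 35 and 15 °C labels is excluded for both by the 989 transcripts that separate 35 from 15 °C without them. With 0 for the 15 °C mean and 1 for the 35 °C mean, replicate 2 at 35 °C had a median position of 1.01. Replicate 3 at 15 °C had a median position of 0. A 25 °C library in its place is not excluded, since the 25 °C libraries also stand at 0. Mixing of a large share of the first into the second is argued against, since the second stood a median of 0% of the way to it. A small carry-over is not excluded. The 217 block transcripts with at least 20 FPKM at 35 °C stood at 0.314% of their 35 °C level in 15 °C replicate 3. In 15 °C replicates 1 and 2 they stood at 0.0237 and 0.0356%. Mixing of the second into the first was not tested. Whether lower depth plays a part was not settled. Their relative depths were the lowest, yet each listed at least 3174 more transcripts above 0 than the other libraries of its group. These measures disagree, and neither was taken on the transcripts above 100 FPKM in which the likeness was seen. Their deviations from the group means correlated at 0.5019 across transcripts, which a shared handling or library batch could give, but the labels name no batch, so a batch cannot be told apart from other shared conditions of these samples, and no biological explanation was tested.

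Other divisions of the libraries were counted for each number of calls. Of the 10 splits of the 6 libraries at 35 and 25 °C, 1 (the real one, 2349) gave as many calls, and the highest other gave 0; for 15 against 25 °C it was 1 of 10 (185, highest other 0), and for 35 against 15 °C 1 of 10 (1677, highest other 2). A set of 10 splits is too few for a share under 0.05. Of the 280 possible splits of the 9 libraries into 3 groups of 3, 100 were counted, the real one and others drawn at random. Only the real one reached its own count for any temperature (2350, against 1444 in the highest other). That share is under 0.05, but the drawn splits that part the 35 °C libraries gave 64 calls at most. A low share thus follows from the likeness of the 35 °C libraries alone and does not test the grouping of the other 6. It does not show why the libraries of a temperature are alike, since the labels do not show separate cultures, and the split with 1444 also keeps the 35 °C libraries together. For the departure from a straight line, 2 of 100 splits, the real one included, reached the real count of 652, and the highest other gave 1650. The share is again under 0.05, but the split with 1650 keeps the 35 °C libraries together as the middle group and mixes the rest. It points to a structure of the samples in which 35 °C differs from both others, so the splits do not single out a departure at 25 °C.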
